A study of Homo sapiens with 9 samples.

How the data were processed

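RNA from cells of a human colorectal cancer line was extracted 24 hours after transfection with KL-FL, KL1 or the empty vector pcDNA3, and 100 ng of total RNA per sample was labelled with a whole-transcript kit, per the labels' protocols. The transfection reagent was either JetPEI or polyethylenimine, and the labels do not say which sample received which. The authors deposited 1 table of log2 expression values for all 9 arrays, with 33297 probe sets. The submitters' processing notes name Partek 6.6. The background correction, normalization and summary method are not given in the sources used here, and the log base was inferred from the range of the values, 1.79 to 12.4. The array medians over all probe sets differ slightly between arrays, and the values were used as deposited. The table holds no detection call, so a dim gene cannot be told from an absent one.

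Probe sets were named through a table pairing them with the platform's gene annotation. Of the 33297, 19181 named 1 gene symbol, 2055 named several and 12061 were unnamed here. Symbols were checked through gene IDs against a current reference, which changed 0 of them, and 38 had no match. Probe sets naming 1 gene were kept, and where several named the same gene, as for 895 genes, the one with the highest mean over the 9 arrays stood for it. This gave 17958 genes. Of the genes named by the rule below, ATF4, RPL9, DXO, CCDC82 and STARD9 have more than 1 probe set, and those of CCDC82 differ in sign in the KL-FL comparison, at 0.14 and -0.028. No array was a copy of another, with correlations between arrays from 0.990 to 0.998.

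Samples were grouped by their titles into control, KL-FL and KL1, with 3 arrays each. A linear model with 3 groups and no covariate was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), so that all groups shared 1 estimate of the spread with 6 residual degrees of freedom. The contrasts were KL-FL minus control, KL1 minus control and KL-FL minus KL1. The labels give each group replicates 1, 2 and 3 without saying what the numbers share. All 3 same-numbered pairs of control and KL1 deviated together, with correlations from 0.113 to 0.322, so the numbers may pair the arrays of that comparison. Deviations were taken from group means, so the 3 values are not independent: a deviation shared by 1 pair would raise all 3. Of the pairs with KL-FL 0 correlated over 0.1, the highest being 0.097, and a pairing there is not excluded. Adjusted p-values are two-sided with Benjamini-Hochberg adjustment over all genes, at a threshold of 0.05. Counts adjusted over the list alone use the same p-values with the adjustment inside the list.

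Gene lists, 37 in all, were fixed before the data were examined, as were the design, the comparisons, the named-gene rule and the alternatives set beforehand. They were tested with limma's camera, which asks whether a list moved relative to other genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over lists. Each was tested again with an estimated correlation and with fry, which asks whether a list's genes moved without comparing them to others. With an estimated correlation 0 lists were called in any comparison, and with fry's test of a common direction 0 as well. fry's test of change in either direction called 2 lists in each comparison with control, the ER chaperones and the PERK/ATF4 targets, and 0 between KL-FL and KL1. The mean and the median of a list differed in sign in 3, 7 and 8 of the 37 lists, of which 0 were called.

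The genes named are KL, the 11 unfolded protein response markers HSPA5, HERPUD1, DNAJB9, XBP1, ATF4, DDIT3, ATF3, TRIB3, ASNS, CHAC1 and SESN2, and the 3 members with the smallest p in each list called. For each comparison with control the rule adds up to 8 genes past the threshold with the largest changes in each direction, or the 5 with the smallest p where fewer than 3 passed. Between KL-FL and KL1 it takes the 3 with the smallest p in each direction. Genes named outside this rule are said to be so.

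The model and camera were tested on simulated arrays of 17958 genes with the spread of the KL-FL comparison, in 20 runs. In those runs limma recovered 62.4% of genes changed by a log2 of 0.25, 95.9% at 0.5, 99.7% at 1 and 99.9% at 2, and 4.69% of its calls were false. Each run changed 200 genes, 50 at each size. The Benjamini-Hochberg cutoff is stricter where fewer genes change, so these shares would overstate recovery in the real comparisons, which had at most 1 call. When nothing was changed limma called at most 1 gene in a run, as many as in each real comparison with control, and camera called 0 lists. How many runs had a call was not kept, so the real calls cannot be set against a rate. Camera called the ER chaperone list in 100% of runs when it was shifted by 0.1. The simulated genes were independent, unlike genes on real arrays. The real arrays also deviated unevenly from their group means, with an SD over genes of 0.094 on KL-FL replicate 3 and 0.051 on control replicate 3.

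Alternatives covered quantile normalization and median centring of the deposited values, filters on dim genes at the 25th and 50th percentiles, every probe set tested, the mean of a gene's probe sets, other variance moderation, array weights, the 6 arrays of each comparison, the replicate number as a block, a 1.5-fold minimum, and leaving out each array in turn. Added after the data were examined were the fits without KL-FL replicate 3 and KL1 replicate 2 together and the contrast of both klotho vectors with control. The 14116 probe sets that name no gene or several were tested separately and not named.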

Results

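Gene expression was measured in a human colorectal cancer cell line 24 hours after transfection with 1 of 3 vectors. KL-FL carried mouse full-length klotho, a membrane protein best known as the co-receptor of the hormone FGF23. KL1 carried the KL1 subdomain of that protein, and the control was the empty vector pcDNA3. Each group had 3 arrays, 9 in all, read on a whole-transcript human array and deposited as log2 expression values. The table held 33297 probe sets with values from 1.79 to 12.4, and 17958 genes were analysed. The number of arrays limits the precision of every value. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these arrays, which may be technical. The series title names the unfolded protein response, the program that raises folding capacity when misfolded protein builds up in the endoplasmic reticulum (ER), and the comparisons below are set out with that question in mind. The array medians over genes ran from 5.38 to 5.42. KL-FL replicate 3 stood apart from the other arrays, with a median correlation of 0.994 to the other 8, and KL1 replicate 2 followed at 0.996, while the remaining 7 lay between 0.997 and 0.998.

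The targeted gene, KL (probe set 7968556), read at the low end of the scale in every group. Its log2 value was 3.05 ± 0.014 (SD, n = 3) in control, 3.19 ± 0.046 (SD, n = 3) with KL-FL and 3.19 ± 0.067 (SD, n = 3) with KL1. All 6 arrays of the klotho groups lay above all 3 controls, with log2 differences of 0.14 (SE 0.040) for KL-FL and 0.15 (SE 0.040) for KL1. Neither passed the limma test over all genes, with adjusted p = 0.637 and 0.927. Of all genes, 10.4% did not overlap between KL-FL and control and 9.47% between KL1 and control, where chance gives 10%. The vectors carry mouse sequence and the probes were designed on the human gene, so the KL reading checks the labels only weakly.

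With full-length klotho, the gene that rose was DDIT3 (probe set 7964460), which encodes CHOP, a transcription factor induced by ER stress. Its log2 value was 7.33 ± 0.13 (SD, n = 3) with KL-FL against 6.68 ± 0.034 (SD, n = 3) in control, a rise of 0.65 (SE 0.059) or 1.56-fold, and 3 of 3 KL-FL arrays lay above every control. ER chaperones and foldases, the proteins that fold newly made secretory proteins, rose as a group by a mean log2 of 0.11 in camera, with 24 of 25 measured members higher (adjusted p = 0.900 with an estimated correlation). Replication-dependent histones fell as a group by a mean log2 of -0.11, with 40 of 44 members lower (adjusted p = 0.900 with an estimated correlation), but this fall rested on KL-FL replicate 3.

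DDIT3 was the only gene of 17958 past the threshold in limma, at adjusted p = 0.0348, and the next smallest adjusted p was 0.363. With array weights the count was 523, 389 higher and 134 lower. On simulated arrays with nothing changed, limma called at most 1 gene in a run, and how many runs had a call was not kept. At an unadjusted p under 0.05 there were 1286 genes, 877 higher and 409 lower, where chance gives 897.9. The DDIT3 call ended in limma without control replicate 1, 2 or 3 (adjusted p = 0.435, 0.427 and 0.268), without KL-FL replicate 1 (0.205) and without KL1 replicate 1, 2 or 3 (0.183, 0.0744 and 0.168). Its log2 change stayed between 0.57 and 0.69 over all 9 arrays left out in turn. The call also ended when each gene's own variance, only the 6 arrays compared or every probe set was used, with adjusted p = 0.186, 0.472 and 0.220. With the replicate number as a block in limma it ended too, with adjusted p = 0.226.

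Other markers of the unfolded protein response did not pass the limma test over all genes. HERPUD1, a component of ER-associated degradation, differed by 0.45 (SE 0.073, adjusted p = 0.408) on the log2 scale and lay above control on 3 of 3 arrays. The 2 groups did not overlap in 10.4% of all genes, where chance gives 10%. HSP90B1 and HSPA5, abundant ER chaperones, differed by 0.21 (SE 0.033) and 0.23 (SE 0.059). The stress-induced transcription factor ATF3 differed by 0.22 (SE 0.051), SESN2 by 0.19 (SE 0.067) and the co-chaperone DNAJB9 by 0.21 (SE 0.14). XBP1 and TRIB3 each differed by less than 0.10. ATF4, the factor that drives DDIT3 transcription when PERK is active, differed by -0.098 (SE 0.049), and its second probe set gave -0.11. These are RNA values, and ATF4 protein was not measured. ASNS and CHAC1, both ATF4 targets, differed by 0.0060 and 0.028, and both signs turn when arrays are centred on their medians.

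The ER chaperone list passed camera at adjusted p = 9.33e-07, and no list passed with an estimated correlation, where the chaperone list had adjusted p = 0.900. None of its members passed over all genes, and 5 did when adjusted over the list alone: HSP90B1, HSPA5, DNAJC3, ERP44 and DNAJB11, the last chosen after its values were seen. DNAJC3, which restrains PERK, differed by 0.30 (SE 0.074) and ERP44 by 0.15 (SE 0.035). Genes of ER-associated degradation and ER-to-Golgi traffic had a mean log2 difference of 0.051, with 26 of 37 higher, and did not pass camera (adjusted p = 0.0753), but did under quantile normalization (adjusted p = 0.00324), without genes below the 50th percentile (adjusted p = 0.0254) and without KL1 replicate 1 (adjusted p = 0.0495) or 3 (adjusted p = 0.0463). Their mean was 0.091 without KL-FL replicate 3 (adjusted p = 0.00013) and was 0.018 without KL-FL replicate 2 (adjusted p = 0.733). Of these, 3 passed when adjusted over the list alone, HERPUD1, SEL1L and EDEM1, again the last chosen after its values were seen. PERK/ATF4 and integrated stress response targets averaged 0.026 with 27 of 44 higher (adjusted p = 0.522), and sensors and transcription factors of the response averaged 0.0057 (adjusted p = 0.842). Without KL-FL replicate 3 these means were 0.061 (adjusted p = 0.0923) and 0.036 (adjusted p = 0.469), while that of PERK/ATF4 targets was 0.014 without KL-FL replicate 1 and 0.0023 without KL-FL replicate 2. Of the PERK/ATF4 targets, 1 passed over all genes, DDIT3, and 3 when adjusted over the list alone: DDIT3, ATF3 and XPOT, the last chosen after its values were seen. The 105 genes of the chaperone, degradation and PERK/ATF4 lists together rose by a mean log2 of 0.055 in camera (p = 9.79e-05; p = 0.282 with an estimated correlation). That mean was 0.029 without KL-FL replicate 2 and 0.090 without KL-FL replicate 3. As a single mean per array they gave an exact two-sided permutation p of 0.40, where 0.10 is the smallest that 3 against 3 arrays allow.

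Camera called 5 lists lower in KL-FL, with no member past the threshold over all genes or adjusted over the list alone. Histones had adjusted p = 9.33e-07, oxidative phosphorylation a mean log2 of -0.052 with 31 of 42 members lower (adjusted p = 0.0014), and cytosolic ribosomal proteins -0.038 with 32 of 45 lower (adjusted p = 0.00559). DNA replication and G1/S genes averaged -0.032 with 24 of 37 lower (adjusted p = 0.0343), and glycolysis -0.038 with 13 of 17 lower (adjusted p = 0.0343). Mitosis and G2/M genes averaged 0.0027 with 23 of 42 higher (adjusted p = 0.942), and ribosome biogenesis genes -0.018 (adjusted p = 0.258); neither was called. All 5 had adjusted p = 0.900 with an estimated correlation. Among histones, H3C6 differed by -0.21 (SE 0.065) and H2BC7 by -0.17 (SE 0.070). COX4I1 and COX6B1, subunits of cytochrome c oxidase, each differed by -0.11, RPL18 by -0.12 and the glycolytic enzyme ALDOA by -0.080. Within the DNA replication list RFC2 differed by -0.17 and POLD1 by -0.13, while CDC6, which loads the replicative helicase, went the other way at 0.14. Without KL-FL replicate 3 none of these 5 lists was called, and the mean changes of histones, oxidative phosphorylation, ribosomal proteins and DNA replication genes were 0.0028, 0.014, 0.0045 and 0.0044, while that of glycolysis was -0.027 (adjusted p = 0.0884). Without that array 3 lists were called: ER chaperones (mean 0.13, adjusted p = 4.33e-08), ER-associated degradation (0.091, adjusted p = 0.00013) and hypoxia targets (-0.046, adjusted p = 0.0172). Without control replicate 2 the 3 lists called were ER chaperones, histones and oxidative phosphorylation (adjusted p = 1.20e-06, 3.51e-06 and 0.00226). Hypoxia targets were also called lower without KL-FL replicate 2 (adjusted p = 0.0326), with proteasome subunits (adjusted p = 0.00439), and without control replicate 1 (adjusted p = 3.73e-08), with sterol genes (adjusted p = 0.000119). Control replicates 1, 2 and 3 alone spread over -0.14, 0.032 and 0.10 in the hypoxia mean. DNA replication also lost its call without control replicate 1 (adjusted p = 0.174), ribosomal proteins without control replicate 3 (adjusted p = 0.127), and glycolysis without KL-FL replicate 1 (-0.028, adjusted p = 0.168) or control replicate 3 (-0.0053, adjusted p = 0.529). Other arrays moved these means the other way: without control replicate 1 glycolysis was at -0.076 (adjusted p = 5.40e-05), and without KL-FL replicate 1 DNA replication was at -0.049. Without KL-FL replicate 2 the means of histones, oxidative phosphorylation, ribosomal proteins, DNA replication and glycolysis were -0.20, -0.11, -0.080, -0.051 and -0.060. Ribosomal proteins, DNA replication and glycolysis were not called under quantile normalization (adjusted p = 0.213, 0.314 and 0.314) or without genes below the 50th percentile (adjusted p = 0.0761, 0.209 and 0.198). Their quantile-normalized means did not shrink, at -0.044, -0.043 and -0.044. The median change of all genes was then -0.012, against 0.0099 in the deposited values. Relative to that median, these lists fell less than in the deposited values.

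Outside these lists, the smallest p-values on the higher side belonged to PLA2G2F, a secreted phospholipase (0.27, SE 0.036), and MIR26A1 (0.32, SE 0.053). On the lower side stood RIMKLA (-0.29, SE 0.042), ST8SIA6 (-0.18, SE 0.031), JOSD2 (-0.21, SE 0.037), MARCHF3 (-0.22, SE 0.042) and PEX39 (-0.29, SE 0.057). None of them passed in limma. Epithelial genes averaged -0.028 (camera adjusted p = 0.146), fibroblast and endothelial markers 0.025 (adjusted p = 0.344) and leukocyte markers 0.014 (adjusted p = 0.837).

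**Figure D1:**
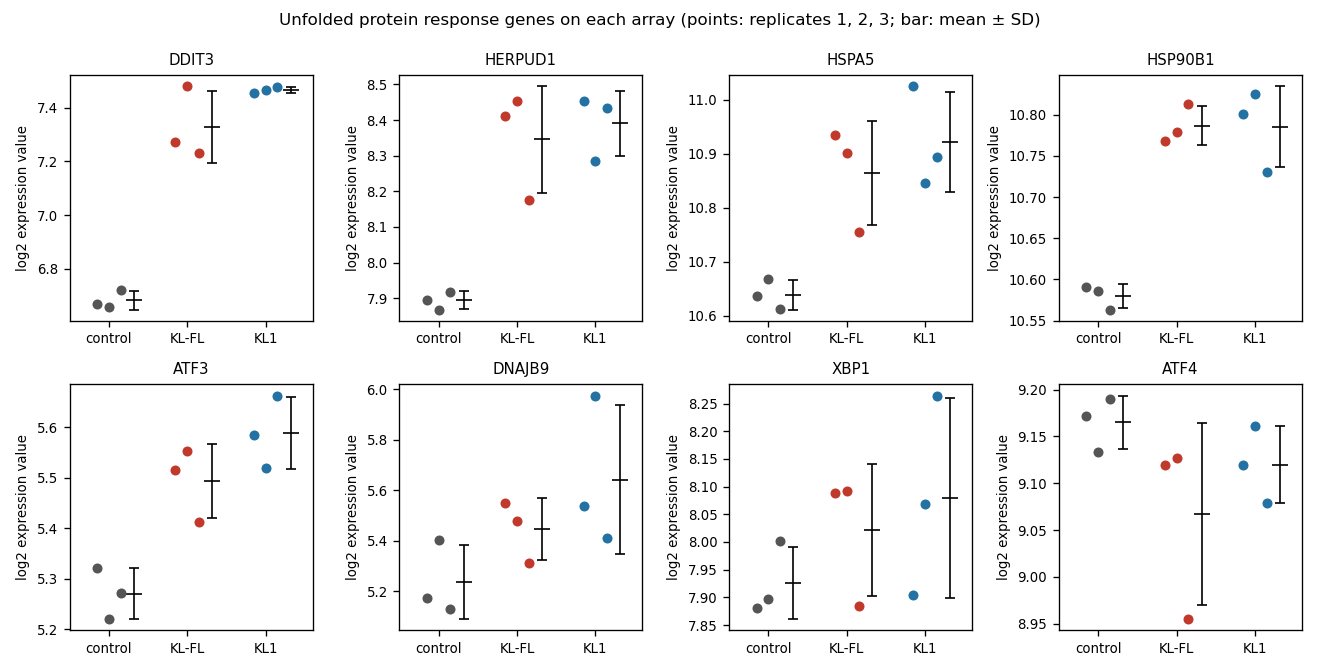
Log2 expression values of 8 unfolded protein response genes on each of the 9 arrays, with points for replicates 1, 2 and 3 of control, KL-FL and KL1 and bars for the mean ± SD (n = 3); the vertical axes do not start at 0. DDIT3 lies at 6.68 in control, 7.33 with KL-FL and 7.47 with KL1, with no overlap between control and klotho arrays, whereas ATF4 RNA is not higher in either klotho group. ATF4 protein was not measured.

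With the KL1 subdomain, DDIT3 was again the gene that rose. Its log2 value was 7.47 ± 0.011 (SD, n = 3) against 6.68 ± 0.034 (SD, n = 3) in control, a rise of 0.78 (SE 0.059) or 1.72-fold, with 3 of 3 KL1 arrays above every control. ER chaperones and foldases rose by a mean log2 of 0.13, with 23 of 25 members higher, and genes of ER-associated degradation and ER-to-Golgi traffic by 0.054, with 25 of 37 higher. Lists of glycolysis, sterol and fatty acid synthesis, DNA replication and mitosis fell by means between -0.051 and -0.027. None of these lists was called with an estimated correlation, where the chaperone list had adjusted p = 0.263 and the others adjusted p = 0.937.

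DDIT3 had adjusted p = 0.00687 in limma and was the only gene past the threshold, with the next at 0.478. With the replicate number as a block 0 genes were called in limma, and DDIT3 had adjusted p = 0.0611. With array weights 2 genes were called, DDIT3 and HERPUD1. At an unadjusted p under 0.05 there were 916 genes, 537 higher and 379 lower, where chance gives 897.9. The DDIT3 call ended in limma without control replicate 1, 2 or 3 (adjusted p = 0.108, 0.104 and 0.0688) and without KL1 replicate 1, 2 or 3 (0.0961, 0.0723 and 0.0975), with the log2 change between 0.77 and 0.80. With each gene's own variance, or every probe set tested, the adjusted p was 0.239 and 0.0519.

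HERPUD1 differed by 0.50 (SE 0.073), SEL1L, its partner in ER-associated degradation, by 0.36 (SE 0.056), ATF3 by 0.32 (SE 0.051), HSPA5 by 0.28 (SE 0.059) and HSP90B1 by 0.21 (SE 0.033). All 5 lay above control on 3 of 3 arrays, and none passed over all genes in limma, with adjusted p from 0.478 to 0.821. The 2 groups did not overlap in 9.47% of all genes, where chance gives 10%. DNAJB9 differed by 0.41 (SE 0.14), HYOU1, an ER chaperone of the HSP70 family, by 0.20 (SE 0.043) and EDEM3 by 0.19 (SE 0.051). SESN2 differed by 0.16, XBP1 by 0.15 and TRIB3 by 0.13. ATF4 differed by -0.045, with -0.099 at its second probe set, ASNS by 0.032 and CHAC1 by -0.0095, a sign that turns under quantile normalization.

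The chaperone list passed camera at adjusted p = 6.12e-12 and had adjusted p = 0.263 with an estimated correlation. Of its members 0 passed over all genes and 10 when adjusted over the list alone, among them HSP90B1, HSPA5, HYOU1, ERP44, DNAJC3 and DNAJB9. The degradation and traffic list had adjusted p = 0.0174, or adjusted p = 0.937 with an estimated correlation, and 2 of its members, HERPUD1 and SEL1L, passed when adjusted over the list alone. PERK/ATF4 targets averaged 0.027 but had a median of -0.0077, with 20 of 44 higher (adjusted p = 0.335) and a mean of 0.016 without KL1 replicate 1, and 2 of them, DDIT3 and ATF3, passed when adjusted over the list alone. The 105 genes together rose by a mean log2 of 0.062 in camera (p = 3.33e-07, or p = 0.173 with an estimated correlation), with an exact two-sided permutation p of 0.10, the smallest possible. The permutation ignored any pairing by replicate number.

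Glycolysis fell by a mean log2 of -0.051 with 15 of 17 members lower (camera adjusted p = 0.0145), mitosis and G2/M genes by -0.027 with 28 of 42 lower (adjusted p = 0.0145), DNA replication genes by -0.030 with 26 of 37 lower (adjusted p = 0.0338) and sterol and fatty acid synthesis genes by -0.029 with 21 of 27 lower (adjusted p = 0.0455). All 4 had adjusted p = 0.937 with an estimated correlation, and none of their members passed over all genes or adjusted over the list alone. CDK1, the kinase that drives mitotic entry, differed by -0.14 (SE 0.040), its activating phosphatase CDC25C by -0.13 (SE 0.047) and the kinetochore gene NUF2 by -0.10 (SE 0.029). RFC2 differed by -0.18 and POLD1 by -0.12, CCNE2 by -0.083, PFKM by -0.15 and FASN by -0.063. The controls alone spread over -0.075, 0.0099 and 0.066 in the glycolysis mean and over -0.071, 0.011 and 0.060 in the sterol mean. In the hypoxia mean they spread over -0.14, 0.032 and 0.10. Without control replicate 2 the chaperone list was the 1 list called, and without KL1 replicate 1 the 3 lists called were ER chaperones, glycolysis and mitosis genes. Without control replicate 3 the sterol mean turned to 0.0010, glycolysis (-0.018, adjusted p = 0.348) and mitosis genes (adjusted p = 0.0505) lost their calls, DNA replication was at -0.045, and leukocyte markers were called higher (adjusted p = 0.0441). Without control replicate 1 glycolysis was at -0.088 and the sterol list at -0.065 (adjusted p = 2.56e-06 for each). DNA replication lost its call without control replicate 1 (adjusted p = 0.0922), and glycolysis without KL1 replicate 2 (adjusted p = 0.0901). Without KL1 replicate 3 the DNA replication, mitosis and sterol lists lost theirs (adjusted p = 0.0827, 0.125 and 0.125). The sterol call also ended without KL-FL replicate 3 (adjusted p = 0.0532) or KL1 replicate 2 (adjusted p = 0.0901). Under quantile normalization glycolysis was the 1 list called lower (adjusted p = 0.0186), and without genes below the 50th percentile 0 lists were called lower by camera. The quantile-normalized means of the sterol, DNA replication and mitosis lists were smaller, at -0.012, -0.014 and -0.010. Hypoxia targets, with a mean of -0.045 (adjusted p = 0.0553), were called lower with the replicate block (adjusted p = 0.0348), without KL-FL replicate 1 (adjusted p = 0.0450) and, with ribosomal proteins (adjusted p = 0.00895), without control replicate 1 (adjusted p = 1.81e-09). Immediate early genes were called higher without KL1 replicate 2 (adjusted p = 0.0215). The smallest p-values on the lower side belonged to GPR137B (-0.22, SE 0.035), SPANXN1 (-0.25, SE 0.049), ASIC1 (-0.23, SE 0.045), DXO (-0.22, SE 0.045) and PXDN (-0.21, SE 0.042), none of which passed in limma. Epithelial genes averaged -0.020 (camera adjusted p = 0.335), fibroblast and endothelial markers 0.020 with 13 of 14 higher (adjusted p = 0.263) and leukocyte markers 0.032 with 11 of 14 higher (adjusted p = 0.0686).

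**Figure D2:**
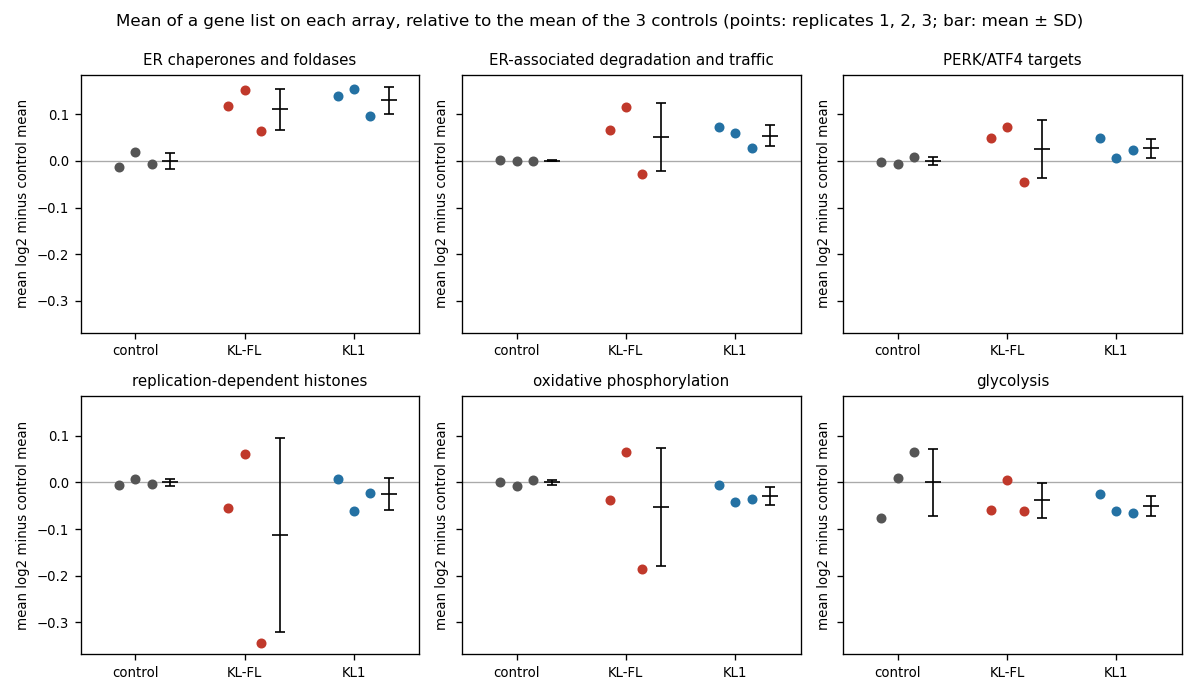
Mean log2 value of 6 gene lists on each of the 9 arrays, relative to the mean of the 3 controls, with points for replicates 1, 2 and 3 and bars for the mean ± SD (n = 3). The ER chaperone mean is above every control on all 6 klotho arrays, from 0.064 to 0.15, while KL-FL replicate 3 alone lies at -0.34 in histones and -0.19 in oxidative phosphorylation.

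Full-length klotho and its KL1 subdomain were compared directly to ask whether the part acts like the whole. No gene passed the threshold between them in limma, where the smallest adjusted p was 0.848 and 906 genes had an unadjusted p under 0.05, against 897.9 by chance. DDIT3 was lower with KL-FL than with KL1 by a log2 of -0.14 (95% interval -0.27 to -0.0034, adjusted p = 0.855). The differences of HERPUD1 (-0.045, 95% interval -0.21 to 0.12), HSPA5 (-0.058, 95% interval -0.19 to 0.075) and HSP90B1 (0.0012, 95% interval -0.074 to 0.076) had intervals that include 0. These intervals do not show that both proteins act alike.

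The ER chaperone list differed by a mean log2 of -0.019 between KL-FL and KL1, with 17 of 25 members lower, and did not pass camera (adjusted p = 0.313). The 105 unfolded protein response genes differed by -0.0066 (camera p = 0.216, exact two-sided permutation p = 0.90), and by 0.028 without KL-FL replicate 3 and 0.0023 without KL1 replicate 1. Camera called them lower without KL-FL replicate 2 (-0.032) and without KL1 replicate 3 (-0.016). Under quantile normalization their means against control were 0.040 with KL-FL and 0.075 with KL1. Under median centring they were 0.022 and 0.058, so under both scalings the difference was more negative than -0.0066. Histones were the 1 list called, lower in KL-FL by -0.087 with 41 of 44 members lower (adjusted p = 6.42e-05; adjusted p = 0.986 with an estimated correlation). Without KL-FL replicate 3 their mean was 0.028 (adjusted p = 0.881), and 2 other lists were called higher, FGF receptor and ERK feedback targets (adjusted p = 0.0279) and mitosis genes (adjusted p = 0.00651). The latter were also called without KL1 replicate 2 (adjusted p = 0.0387). Without KL-FL replicate 2, oxidative phosphorylation (adjusted p = 0.000355), ribosomal proteins (adjusted p = 0.00211) and proteasome subunits (adjusted p = 0.00558) were called lower in KL-FL beside histones (-0.17). The smallest p-values belonged to CCDC68 (0.24, SE 0.039), CCDC82 (0.24, SE 0.039) and STARD9 (0.38, SE 0.062) on the higher side and EMILIN2 (-0.18, SE 0.034), JOSD2 (-0.19, SE 0.037) and SOX14 (-0.16, SE 0.032) on the lower side.

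The log2 changes of the KL-FL and KL1 comparisons correlated across genes at Pearson r = 0.548 and Spearman rho = 0.495, and 68.1% of genes had the same sign; genes are not independent replicates. Both comparisons use the same 3 controls, and 100 simulated draws of unchanged groups against shared controls gave a mean r of 0.499, at most 0.528, and 66.7% of genes with the same sign. The covariance was 0.00293, against a simulated mean of 0.00183 and a range of 0.00162 to 0.00200. Without KL1 replicate 1 r was 0.412 and without KL-FL replicate 2 it was 0.461, both under the simulated mean for 9 arrays; no groups of these smaller sizes were simulated. DDIT3 was called higher in both comparisons, and an overlap of calls under shared controls was not simulated. The 3 controls are too few to split, so part of the excess may come from the shared controls.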

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

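The limma and camera tests and the counts over other splits of the arrays were planned. The tests that weigh explanations, and those without both arrays that stand apart, were chosen after the result was seen.

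The histone list differed between KL-FL and KL1 by a mean log2 of -0.087 in a camera test of the difference itself (adjusted p = 6.42e-05; adjusted p = 0.986 with an estimated correlation), and it fell with oxidative phosphorylation and ribosomal protein genes against control. Without KL-FL replicate 3 the histone mean change against control was 0.0028 and 0 of the 3 lists were called lower, so the deviation of that array may account for the calls. Whether the 3 KL-FL arrays share a change was not settled. KL-FL replicate 2 lay above every control in all 3 lists, by at least 0.046 over the control mean. That array was higher in general, with a median over genes of 5.417 against 5.383 to 5.399 in the controls. It also lay above the control mean in p53 targets (0.069) and leukocyte markers (0.061). Its height in the 3 lists may therefore not belong to these lists. KL-FL replicate 1 lay below every control in all 3, at -0.055 in histones, -0.037 in oxidative phosphorylation and -0.037 in ribosomal proteins. A uniform shift of KL-FL replicate 3 is argued against, since the median of all its genes differed from controls by -0.013, where its histone mean was -0.34. A distortion that differs between probe sets is not excluded. Over all probe sets its median was higher, at 4.755 against 4.697 to 4.709 in the controls. The fall was also broad. Of the fixed lists only ER chaperones (0.064), fibroblast and endothelial markers (0.022) and intestinal differentiation markers (0.008) lay above the control mean on it. What set that array apart, in the culture or in its preparation, stays open.

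ER chaperone genes were higher in both klotho groups. An overall shift of the klotho arrays is argued against by the median change of all genes, at most 0.0099, against list means of 0.11 and 0.13. The 2 arrays that stand apart are not the source either, since without KL-FL replicate 3 and KL1 replicate 2 the smaller list mean was 0.12 and lay above every control. The load of any overexpressed protein that enters the ER cannot be told apart from an action of klotho: the vectors code for klotho or a part of it, the protein made was not measured, the KL-FL and KL1 lists differed by -0.019, and the design has an empty vector but no unrelated secreted or membrane protein. An action of klotho itself stays among the open explanations, as untested.

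KL1 replicate 2 lay nearer to the controls than to KL-FL in most probe sets with the largest changes, though not always beside the controls. Of the 26 that differed at least 2-fold between KL-FL and control, KL1 replicate 2 was closer to the control mean in 24, KL1 replicate 1 in 4 and KL1 replicate 3 in 13. These counts include probe sets where an array lay beyond the controls, on the side away from KL-FL. In probe set 7896313 KL1 replicate 2 read 3.52, where the controls read 4.25 to 5.41. In probe set 7893267 it read 3.29, where the controls read 3.65 to 4.36. In both, KL-FL was higher than control. A control sample under a wrong label is argued against by DDIT3, which lay 0.78 above the control mean on that array, where the control SD was 0.034. A preparation batch shared by the controls and KL1 replicate 2 cannot be told apart from other sources, because the labels give no batch; the most changed probe set read 6.39 there. No biological explanation was tested.

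CCDC68, CCDC82, STARD9 and SOX14 lay on opposite sides of the control mean on all KL-FL and all KL1 arrays, with KL-FL minus KL1 log2 differences of 0.24, 0.24, 0.38 and -0.16. This holds for the brightest probe set of each. The other CCDC82 probe set differed from control by -0.028 with KL-FL and -0.11 with KL1. The other STARD9 probe sets differed by 0.18 and 0.072 with KL-FL and by -0.0046 and -0.033 with KL1. They were named because they had the smallest p in that comparison, and the difference did not pass in limma (adjusted p from 0.848 to 0.855).

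With 6 arrays there are 10 splits into 3 and 3, too few for a share under 0.05. For genes, the real split of KL-FL and control gave 1 and the highest other 0, that of KL1 and control 1 and 0, and that of KL-FL and KL1 0 and 2. For lists, the real counts were 6, 6 and 1 and the highest others 10, 6 and 9. The replicate numbers may pair control and KL1, and the real split parts all 3 pairs. The 3 other splits that do so gave at most 0 genes and 5 lists, and the remaining 6 splits part 1 pair each. Splits with counts as large, the real one included, numbered 1, 1 and 10 for genes and 7, 2 and 10 for lists. Camera thus called lists in splits that mix the groups. A structure of the arrays beyond their groups, and correlation between a list's genes above the preset 0.01 (estimated at 0.547 for histones), were not tested apart.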

How the results depend on the processing

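The fits without KL-FL replicate 3 and KL1 replicate 2 together, and the contrast of both klotho vectors with control, were chosen after the data were examined. Where no value is said to show it, the cause of a change was not tested. For KL-FL minus control the gene count was 0 with every probe set tested, with no variance moderation and with the 6 arrays compared, and 523 with array weights (389 higher, 134 lower), which gave KL-FL replicate 1 a weight of 6.76 and KL-FL replicate 3 a weight of 0.265; it ranged from 0 to 1 over leaving out each array. With every probe set, limma gave 2410 and 1517 at an unadjusted p under 0.05 in the comparisons with control. Without both arrays that stand apart the 1 gene was HERPUD1 (adjusted p = 0.0126). Without KL1 replicate 2 the 1 gene was TOB2 (-2.43, chosen after its values were seen), not DDIT3. For KL1 minus control the count was 0 with every probe set or no moderation, 2 with array weights, 0 to 1 over leaving out each array, and 2 without both arrays that stand apart (DDIT3 and HERPUD1). For KL-FL minus KL1 it was 1 with no moderation (ABCA3, chosen after its values were seen) and 1 with array weights (STARD9). For both vectors minus control it was 4 with array weights, 0 to 3 over leaving out each array and 3 without both arrays. The KL difference with KL-FL was 0.17 with array weights, past the threshold (adjusted p = 0.0359).

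The replicate numbers may pair the arrays of control and KL1, where 3 of 3 same-numbered pairs correlated over 0.1, though these 3 values are not independent. None of the pairs of KL-FL with either group correlated over 0.1 (lowest -0.095, highest 0.097). Of all arrays, 7 of 9 correlated best with their own number. The block was fitted over all 9 arrays, so it gives KL-FL the same number effects. With the replicate number as a block the gene count was 0 in each comparison with control, where DDIT3 had limma adjusted p = 0.226 with KL-FL and 0.0611 with KL1, and 0 between KL-FL and KL1, list counts were 5, 8 and 1 (glycolysis lost in KL-FL, hypoxia targets and aminoacyl-tRNA synthetases gained in KL1, no other call changed), the KL differences 0.14 and 0.15, the unfolded protein response means 0.055, 0.062 and -0.0066, the correlation of changes 0.548 and the count for both vectors 1.

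List counts for KL-FL minus control were 0 with an estimated correlation and with fry, 3 without both arrays and 3 to 8 over leaving out each array. For KL1 minus control they were 0 with each of these tests, 3 without genes below the 50th percentile and 1 to 7. For KL-FL minus KL1 they were 0 with each test and 1 to 4. The means of the 105 unfolded protein response genes, 0.055 and 0.062, no longer passed with an estimated correlation. They were 0.040 and 0.075 under quantile normalization and 0.022 and 0.058 under median centring. The KL-FL minus KL1 mean of these genes was 0.013 with array weights, 0.028 without both arrays and -0.0099 without genes below the 50th percentile. Under both scalings it was more negative than the -0.0066 of the deposited values. It ran from -0.032 to 0.028 over leaving out each array, and camera called it lower with the filter on dim genes, without KL-FL replicate 2 and without KL1 replicate 3. The same ranges were 0.029 to 0.090 and 0.053 to 0.071 against control, 0.126 to 0.167 and 0.110 to 0.176 for KL, and 0.412 to 0.614 for the correlation of changes.

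Signs turned for ASNS in KL-FL (-0.0030 quantile, -0.028 centred, -0.0021 without control replicate 3), CHAC1 in KL-FL (-0.0060 centred, -0.072 without KL-FL replicate 1, -0.013 without control replicate 3) and CHAC1 in KL1 (0.011 quantile, 0.035 array weights, 0.048 without control replicate 1, 0.087 without KL1 replicate 2 and without both arrays). Without KL-FL replicate 3, alone or with KL1 replicate 2, the KL-FL means turned to 0.0044 (DNA replication), 0.0028 (histones), 0.014 (oxidative phosphorylation) and 0.0045 (ribosomal proteins), and without KL-FL replicate 2 they were -0.051, -0.20, -0.11 and -0.080. The histone KL-FL minus KL1 mean turned to 0.028 and, without both arrays, 0.0099, and was -0.17 without KL-FL replicate 2. The sterol mean in KL1 turned to 0.0010 without control replicate 3 and was -0.065 without control replicate 1. Of the named genes only DDIT3 had a call to lose, in the comparisons with control: it lost it in 11 of 18 alternatives with KL-FL and in 8 of 18 with KL1, and again with every probe set tested. The list means given kept direction and call in 151 settings, lost the call in 56, gained it in 6 and turned in 11. Lists called higher and lower in KL-FL, 1 and 5, were 2 and 2 under quantile normalization and without genes below the 50th percentile; in KL1, 2 and 4 became 3 and 1, and 3 and 0. The median change of all genes stayed within -0.024 to 0.0099 under every scaling. The table gives no background signal, so what is too dim to measure cannot be said.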

Other observations

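The list tests of each klotho vector against control were planned; the contrast of both vectors with control, the permutation over 9 arrays and the tests of single probe sets were chosen after the data were examined.

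None of the lists named in this paragraph was called against control by camera on the deposited values of all 9 arrays, with every gene and no block. FGF receptor and ERK feedback targets averaged a log2 of 0.024 with KL-FL and -0.017 with KL1 (camera adjusted p = 0.948 and 0.198), and 1 member passed when adjusted over the list alone, the ERK phosphatase DUSP6 at -0.17 with KL-FL, chosen after its values were seen. Wnt and beta-catenin targets averaged 0.0081 and 0.0069 (adjusted p = 0.948 and 0.943), and insulin, IGF1 and FOXO genes -0.023 and -0.015 (adjusted p = 0.115 and 0.335). p53 targets averaged 0.021 and 0.0040 (adjusted p = 0.554 and 0.937), apoptosis regulators 0.0071 and 0.012 (adjusted p = 0.947 and 0.937) and the heat shock response 0.012 and 0.0061 (adjusted p = 0.948 and 0.937). Aminoacyl-tRNA synthetases, many of them ATF4 targets, averaged 0.018 and 0.036 (adjusted p = 0.621 and 0.0846), and were called higher with KL1 under quantile normalization (adjusted p = 0.0111), without genes below the 50th percentile (adjusted p = 0.00824), with the replicate block (adjusted p = 0.0348) and without KL1 replicate 3 (adjusted p = 0.0128). KL-FL replicate 3 moved these KL-FL means: without it they were 0.059 for FGF receptor and ERK feedback targets, 0.033 for Wnt, 0.00066 for insulin, IGF1 and FOXO, 0.052 for p53, 0.041 for apoptosis, 0.044 for heat shock and 0.057 for the synthetases, with adjusted p from 0.0884 to 0.606. The KL-FL minus KL1 mean of FGF receptor and ERK feedback targets was then 0.076 and was called higher (adjusted p = 0.0279).

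With the mean of both klotho vectors set against control, DDIT3 was the 1 gene past the threshold in limma, at 0.71 (SE 0.051, adjusted p = 0.00442) and higher on 6 of 6 arrays; leaving out control replicate 1, 2 or 3 raised its adjusted p to 0.0945, 0.0914 or 0.0586. HERPUD1 (0.47) and HSP90B1 (0.21) came next, each with adjusted p = 0.277 and each higher on 6 of 6 arrays. The share of all genes higher or lower on 6 of 6 arrays was not counted. The hypothesis that a klotho vector of either length goes with higher ER chaperone genes was put to an exact two-sided permutation of the list mean, a difference of 0.12, over the 84 splits of 9 arrays into 6 and 3. The permutation gave p = 0.0119, the smallest possible, and the chaperone list was the 1 list of 37 to reach it. Adjusted over the 37 lists the permutation p was 0.440, the lowest that 1 list alone at the smallest p can reach, so the adjusted value was fixed by the design and decides nothing. The list was also picked after it was seen to be higher, and the hypothesis stays open.

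The largest changes in the table belonged mostly to probe sets that name no gene here; of the 26 that differed at least 2-fold between KL-FL and control, 4 name 1 gene, TOB2 on a pair of them and the small nuclear RNA genes RNU5D-1 and RNU5F-1. Probe set 8108180, unnamed here, read 5.92, 6.51 and 6.77 in the controls and 6.39 on KL1 replicate 2, but 3.30 to 3.90 on the other 5 arrays. Probe sets 8113120 and 8165707, both annotated as TOB2, hold identical values, from 9.71 to 10.4 in the controls and 10.1 on KL1 replicate 2, and 7.35 to 7.98 elsewhere, a log2 difference of -2.43 for KL-FL (SE 0.58). Another TOB2 probe set, 8076331, read 6.95 to 7.25 on all arrays, so the fall does not belong to the gene as a whole. Probe set 7896748, unnamed here, went the other way, from 6.82 to 7.63 in the controls and KL1 replicate 2 and from 8.73 to 9.33 elsewhere. Over every probe set 0 of the 26 that differed at least 2-fold passed in limma. All these probe sets were chosen after their values were seen.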
